A study of Mus musculus with 20 samples.

How the data were processed

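Polyadenylated RNA of the left atrium and left ventricle of C57BL/6J pups was sequenced on postnatal day 4, after hyperoxia at 100% oxygen or room air at 21%, with 5 libraries in each of 4 groups. Per the labels a stranded mRNA kit was used and the dams were rotated between the oxygen levels. For the RNA extraction the sample labels named a Direct-zol kit and the series description an RNeasy kit, and which was used was left open. The deposited files hold raw read counts per gene symbol as the authors made them, not normalized, for 55367 genes in 2 columns, of which 0 were left unused. Per the submitters' processing notes, fastp 0.20.1, STAR 2.7.6a, Subread 2.0.1, featureCounts and Salmon 1.3.0 were used with GRCm38.p6. The annotation release and the strand setting of the counting were not stated. Total counts ranged from 26510081 to 38244117 per library. The smallest chi-square per degree of freedom between libraries of 1 group was 13.26, so none was a copy or technical repeat of another.

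Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups (16598 genes) and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion and 1 coefficient per group was fitted to all 20 libraries (common biological coefficient of variation 0.183). Contrasts gave hyperoxia against room air in each chamber, the difference between these responses (atrium minus ventricle), and atrium against ventricle at each oxygen level. Every adjusted p of a gene is from the edgeR quasi-likelihood F-test with Benjamini-Hochberg correction over the 16598 genes, and a gene passed at an adjusted p under 0.05. Standard errors are the log2 difference divided by the square root of F. CPM use TMM-scaled library sizes.

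Before the data were examined, 33 gene lists of pathways and cell states and 20 lists of cell type markers were written down, together with the tests, the rule for naming genes and the first set of other settings. Lists with at least 3 measured members were tested on voom values with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each corrected over the 53 lists of a comparison. Camera compares a list with all other genes, while fry tests whether the genes of a list move 1 way on balance. Members were counted as higher or lower by the edgeR test. Counts adjusted over the list alone correct the same p within the list. Lists share members, and many of their genes are expressed in several cell types of the heart.

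Genes were named by rule. In each hyperoxia comparison these were the 6 higher and 6 lower genes with the largest log2 difference among those passing, with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. The chamber comparisons used the same rule with 4 genes each way. The test of the difference used the 5 largest and 5 smallest values with at least 5 CPM in at least 1 group. For each list described the rule took up to 4 members with the smallest p, or 3 for cell type lists. In both hyperoxia comparisons 8 genes were always named (Fasn, Scd1, Cdkn1a, Nqo1, Mki67, Nppa, Myl2 and Vegfa), and in the chamber comparisons Nppa, Myl7, Myl2 and Irx4. Predicted gene models, pseudogenes, Xist and Y-linked genes were counted but not named by size. Positions and exon lengths, the latter over all annotated exons of a gene, were taken by symbol from the GENCODE annotation of the same build. Some genes that the rule picks are not reported here. Of the 111 genes named, 33 share exonic bases with another annotated gene, 4 of them on the same strand.

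The length slope of a library is the slope, over 11133 genes of at least 5 CPM, of log2 CPM minus the mean of its chamber on log2 exon length. For 2 lists each member was matched to its 50 nearest genes in log2 exon length and log2 mean CPM. The excess of a list in a library is the median, over members, of log2 CPM minus the mean of the matched genes. Sex is not in the labels, so Y-linked reads (Ddx3y, Kdm5d, Eif2s3y and Uty) were compared with those of Xist. Where a group total was 1 to 3 counts, the ratio of group totals per scaled library size carries a 95% exact binomial interval. Intervals and floors cover counting error only.

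Simulated counts were drawn from the observed group means and dispersions, with 67, 67 and 66 genes changed by 1.5-fold, 2-fold and 4-fold in each comparison. The test was checked on these counts. At 1.5-fold, 2-fold and 4-fold it recovered 52.2%, 91% and 98.5% of the changed genes for hyperoxia in the atrium (16354 genes tested), with 6.9% of calls false. In the ventricle it recovered 47.8%, 83.6% and 100% (16391 genes, 3.1% false), and between the chambers in room air 56.7%, 86.6% and 100% (16236 genes, 3.6% false). In the data far more genes passed (43.9% in the atrium), and no difference in length slope or sex within a group was simulated. The percentages recovered and false therefore need not hold for the data. Of 100 unchanged simulated lists camera called 0, and it called a list of 30 genes shifted by 0.5 log2 (adjusted p = 7.7e-26). The simulated genes were drawn independently of each other. This check therefore says nothing about lists whose members vary together, such as the ribosomal protein genes with an estimated correlation of 0.93.

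The first set of other settings held other scalings and filters, DESeq2 1.42.0, limma voom with quality weights, fits on the compared libraries alone, replicate numbers as a block, Y-linked reads as a covariate, and each library left out in turn. Settings chosen after seeing the data left out the 3 libraries tilted towards short transcripts or 3 ventricular libraries that lay apart on principal components. Others kept the libraries with more Y-linked than Xist reads alone, or took the length slope, ventricular Myl7, or the slope with Y-linked reads as covariates. Each count was recomputed for 100 splits of the libraries, drawn from 126 for 2 groups and 31752 for the difference between responses. The overlap of the 2 responses was compared with 100 permutations of the oxygen labels. No library was left out of the reported fit.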

Results

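The series measured polyadenylated RNA by sequencing in the left atrium and the left ventricle of C57BL/6J mouse pups that breathed 100% oxygen (hyperoxia) or room air (21% oxygen) from birth to postnatal day 4. Each of the 4 groups (hyperoxic atrium, room-air atrium, hyperoxic ventricle, room-air ventricle) held 5 libraries, 20 in all. Total counts over genes ranged from 26510081 to 38244117 per library, and 16598 of the 55367 genes listed passed the expression filter. Values are CPM (counts scaled to library size) as mean ± SD with n = 5 libraries per group. Log2 differences carry their standard error (SE). Positions are those of GRCm38.

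Chamber and oxygen were not the only measured differences between the groups. All 5 libraries of both room-air groups had more Y-linked than Xist reads. This held for 1 of 5 hyperoxic atria (number 2) and 2 of 5 hyperoxic ventricles (numbers 2 and 6). The slope of log2 CPM on log2 exon length, which is below 0 where short transcripts take a larger share, was -0.294 in hyperoxic atrium 2, -0.289 in hyperoxic atrium 4 and -0.225 in room-air ventricle 4, and between -0.070 and 0.135 in the other 17 libraries. The atrial light chain Myl7 averaged 231 ± 203 CPM in room-air ventricles and 38.9 ± 52.9 CPM in hyperoxic ventricles, against 7010 ± 837 CPM in room-air atria. Room-air atrium 1 held 328 CPM of the ventricular light chain Myl2, against 7.42 to 15 CPM in the other 4.

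**Figure D1:**
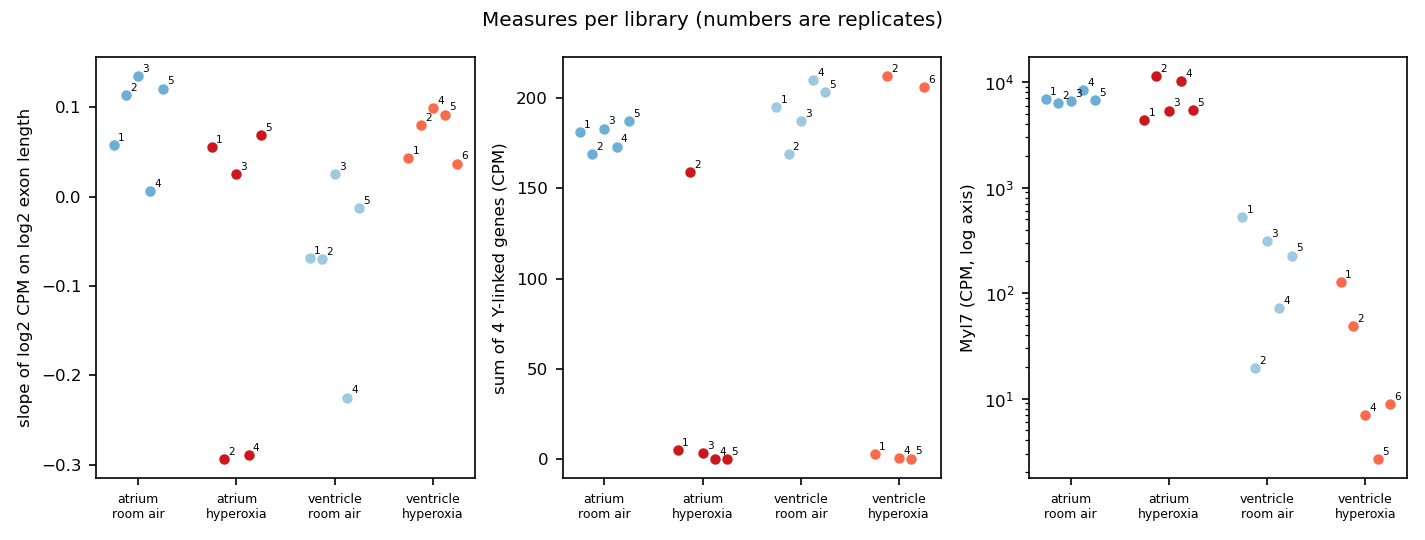
Slope of log2 CPM on log2 exon length, summed CPM of 4 Y-linked genes, and Myl7 CPM (log axis) for each of the 20 libraries, with replicate numbers beside the points and groups on the x axis. The slopes of hyperoxic atria 2 and 4 (-0.294 and -0.289) and room-air ventricle 4 (-0.225) lie below the rest.

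The first comparison asked which transcripts differed in the left atrium after hyperoxia. The natriuretic peptide genes Nppa and Nppb rose, as did most members of the p53, amino acid and heat shock lists, and most members of the conduction, endothelial and fibroblast lists fell. With an estimated correlation camera called the p53 and amino acid lists (adjusted p = 0.0081 and 0.035) and not the other 4 (0.099, 0.22, 0.096 and 0.13). Nppb, which encodes B-type natriuretic peptide (chromosome 4, 147985788 to 147987205), rose from 16 ± 4.05 to 1330 ± 313 CPM, 83.2-fold. Nppa, which encodes the atrial natriuretic peptide, rose from 6790 ± 816 to 20900 ± 5640 CPM, 3.08-fold. Nmrk2, a nicotinamide riboside kinase of NAD synthesis (chromosome 10, 81198170 to 81202051), rose from 6.83 ± 4.51 to 873 ± 314 CPM. Gdf15, a stress-induced cytokine (chromosome 8, 70629393 to 70632456), rose from 1.5 ± 0.332 to 49.3 ± 11.9 CPM. Cdkn1a, a cell cycle inhibitor induced by p53, rose from 45.4 ± 3.17 to 238 ± 24.0 CPM, 5.24-fold.

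In the left atrium 7291 of 16598 genes passed the edgeR test in hyperoxia, 3271 higher and 4020 lower, of which 783 and 1064 differed by 2-fold or more. Which side held more genes depended on the setting: 3678 were higher and 3573 lower with upper-quartile scaling, 3863 and 3210 with the 1 CPM filter, 3719 and 3404 on the compared libraries alone, and 3931 and 3263 without hyperoxic ventricle 5. In these settings the median gene moved by log2 0.045, 0.076, 0.063 and 0.075, so the turn went with a shift of scale. Hyperoxic ventricle 5 is not one of the libraries compared here. The largest increases also included the claudin Cldn23 (log2 6.04, SE 0.53) and Chac1, an enzyme that degrades glutathione (log2 5.21, SE 0.42). The vomeronasal receptor gene Vmn2r3 had 2070 counts in the hyperoxic atria and 3 counts, all in number 1, in the room-air atria. This is a ratio of 714 with a 95% exact counting interval of 244 to 3460. Its fitted log2 difference was 9.17, and 11.52 without room-air atrium 1. The largest decreases were those of Clca3a2, a chloride channel accessory protein, at -3.69 (SE 0.32), and the kinase gene Sbk3 at -3.50 (SE 0.48). They were followed by the muscle peptidase gene Ky at -3.18 (SE 0.26), the collagen Col22a1 at -2.96 (SE 0.45), the peptidase inhibitor Pi15 at -2.65 (SE 0.15) and the claudin Cldn11 at -2.63 (SE 0.40). Sbk3 fell from 601 ± 67.1 to 53.1 ± 14.7 CPM and Clca3a2 from 108 ± 14.2 to 8.38 ± 3.07 CPM.

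Most members of the stress-response lists rose in the hyperoxic atrium. Among 34 measured p53 targets 26 rose, 2 fell and 6 did not pass the test (27 higher and 2 lower adjusted over the list alone), including Sesn2 at log2 2.51 and the nuclease gene Aen at 1.85 (camera, adjusted p = 6.3e-14). Of 30 genes of ER stress and the amino acid response 18 rose and 12 did not pass (19 rose adjusted over the list alone), including asparagine synthetase, Asns, from 4.30 ± 0.384 to 133 ± 20.3 CPM, and the pseudokinase gene Trib3 at log2 4.76 (camera, adjusted p = 7.8e-13). Both calls held with an estimated correlation, with adjusted p = 0.0081 and 0.035. Among 16 heat shock and folding genes 14 rose, over all genes and adjusted over the list alone, including the chaperone Hspa1a at 3.26 and the small heat shock protein Hspb1 at 1.75 (camera, adjusted p = 6.1e-10, and adjusted p = 0.099 with an estimated correlation). Of 28 NRF2 antioxidant genes 17 rose and 11 did not pass, with the same counts adjusted over the list alone, including Osgin1 at 2.87 and sulfiredoxin, Srxn1, at 1.5 (camera, adjusted p = 9.2e-07, and adjusted p = 0.099 with an estimated correlation). Nqo1, another NRF2 target, was 9.64 ± 0.580 CPM in hyperoxia and 9.30 ± 1.28 CPM in room air (adjusted p = 0.78).

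Some genes on the fetal side of cardiomyocyte maturation and some inflammatory genes also rose. Of 18 fetal-side genes 9 rose and 9 did not pass (10 rose adjusted over the list alone), including the stress-responsive titin-binding protein Ankrd1 from 1210 ± 75.0 to 3780 ± 558 CPM and the RNA-binding protein Igf2bp2 at log2 1.38 (camera, adjusted p = 0.00034, and adjusted p = 0.035 with an estimated correlation). Among 22 genes of inflammatory cytokines and adhesion 12 rose, 2 fell and 8 did not pass (14 and 2 adjusted over the list alone), including the monocyte chemokine Ccl2 at 2.30 and the adhesion molecule Icam1 at 1.0 (camera, adjusted p = 7.2e-05, and adjusted p = 0.034 with an estimated correlation). Of 12 macrophage markers 8 rose and 4 did not pass, with the same counts adjusted over the list alone, including Cd68 from 8.27 ± 1.12 to 23.6 ± 5.77 CPM and the immunoglobulin receptor Fcgr1 at 1.65 (camera, adjusted p = 0.00012, and adjusted p = 0.21 with an estimated correlation).

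Most genes of atrial electrical function and atrial identity fell. Of 28 genes of calcium handling and ion channels 19 fell, 1 rose and 8 did not pass (19 and 2 adjusted over the list alone), including the cardiac potassium channel Kcnh2 from 190 ± 8.14 to 80.2 ± 9.77 CPM (camera, adjusted p = 2.5e-05, and adjusted p = 0.035 with an estimated correlation). Among 17 genes of the pulmonary vein, sinus node and conduction system 12 fell and 5 did not pass (14 fell adjusted over the list alone), including Etv1 at log2 -1.09 (camera, adjusted p = 1.7e-05, and adjusted p = 0.22 with an estimated correlation). Of 20 genes of atrial cardiomyocyte identity 12 fell, 3 rose and 5 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.014, and adjusted p = 0.63 with an estimated correlation). The connexin gene Gja5 fell from 247 ± 28.8 to 73.2 ± 14.8 CPM and the transcription factor gene Tbx5 from 186 ± 24.0 to 85.4 ± 10.3 CPM, while Nppa, of the same list, rose.

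Vascular and connective tissue lists had mostly lower members. Among 15 endothelial markers 13 fell, 1 rose and 1 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.00014, and adjusted p = 0.096 with an estimated correlation). The endothelial claudin Cldn5 fell from 24.7 ± 1.34 to 7.99 ± 1.94 CPM, while the sialomucin Emcn rose from 102 ± 8.98 to 170 ± 17.1 CPM. Of 12 fibroblast markers 10 fell and 2 rose, with the same counts adjusted over the list alone, including the matrix proteoglycan lumican, Lum, at log2 -1.34 and Pi16 at -1.70 (camera, adjusted p = 7.2e-05, and adjusted p = 0.13 with an estimated correlation). Among 34 collagens and fibrosis genes 19 fell, 7 rose and 8 did not pass (19 and 8 adjusted over the list alone), with Col6a3 at -1.55 and the secreted phosphoprotein osteopontin, Spp1, at 4.35. For this list camera had adjusted p = 0.031, 0.75 with an estimated correlation and 0.15 without the 3 libraries tilted towards short transcripts. Of 21 genes of angiogenesis and VEGF signalling 15 fell and 6 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 7.8e-05, and adjusted p = 0.21 with an estimated correlation).

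Ribosomal protein genes and nuclear genes of oxidative phosphorylation were higher in the hyperoxic atria, 2 of which tilted towards short transcripts. Of 8 mitochondrially encoded mRNAs 1 rose and 7 did not pass, with a median log2 difference of -0.03 (camera, adjusted p = 0.64). All 38 ribosomal protein genes rose, with a median log2 difference of 0.79 (camera, adjusted p = 4e-11, and adjusted p = 0.55 with an estimated correlation), and the count adjusted over the list alone was also 38. Without the 3 tilted libraries the median was 0.35 and 30 of the 38 rose. Of 53 nuclear genes of oxidative phosphorylation 46 rose and 7 did not pass (51 rose adjusted over the list alone), with a median of 0.65 (camera, adjusted p = 2.6e-10, and adjusted p = 0.63 with an estimated correlation). Without the 3 tilted libraries their median was 0.21 and 20 of the 53 rose, and camera gave adjusted p = 0.22 with the length slope and the Y-linked reads as covariates. Rps19, a ribosomal protein gene, was 433 ± 182 CPM in hyperoxia and 207 ± 25.8 CPM in room air, and the respiratory chain subunit gene Cox6a2 was 1020 ± 438 and 437 ± 44.4 CPM. Among 33 genes of fatty acid uptake and oxidation 13 rose, 4 fell and 16 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.026, adjusted p = 0.66 with an estimated correlation and 0.19 without the tilted libraries). The thioesterase gene Acot2 rose by log2 1.20.

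Of the genes named in advance, Vegfa rose from 123 ± 12.3 to 195 ± 39.7 CPM (log2 0.67, adjusted p = 0.00078). In the libraries with more Y-linked than Xist reads, of which 1 was a hyperoxic atrium, Vegfa was at 0.43 and did not pass (adjusted p = 0.13). The lipogenic enzyme gene Fasn was at log2 -0.49 (adjusted p = 0.0061), the proliferation marker Mki67 at -0.36 (adjusted p = 0.013) and the desaturase gene Scd1 at -0.01 (adjusted p = 0.95). With the length slope as a covariate Fasn had log2 -0.21 (adjusted p = 0.067) and Mki67 -0.18 (adjusted p = 0.11). Myl2 was at log2 -2.72 (adjusted p = 0.021) and at 0.17 (adjusted p = 0.69) without room-air atrium 1. The Myl2 call was lost in 11 of 36 settings. Besides that one these were no filter on low counts, voom quality weights, only the libraries compared, Y-linked reads as a covariate alone or with the length slope, and both replicate blocks. The others left out the 3 tilted libraries or hyperoxic atrium 2, or kept the libraries with more Y-linked than Xist reads. With both the Y-linked reads and the length slope as covariates 4538 genes passed, and Nppa had log2 0.66 (adjusted p = 0.39). Camera called 20 of 53 lists in this comparison, a number that 31 of 100 splits of the 10 atrial libraries reached, the real split included.

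**Figure D2:**
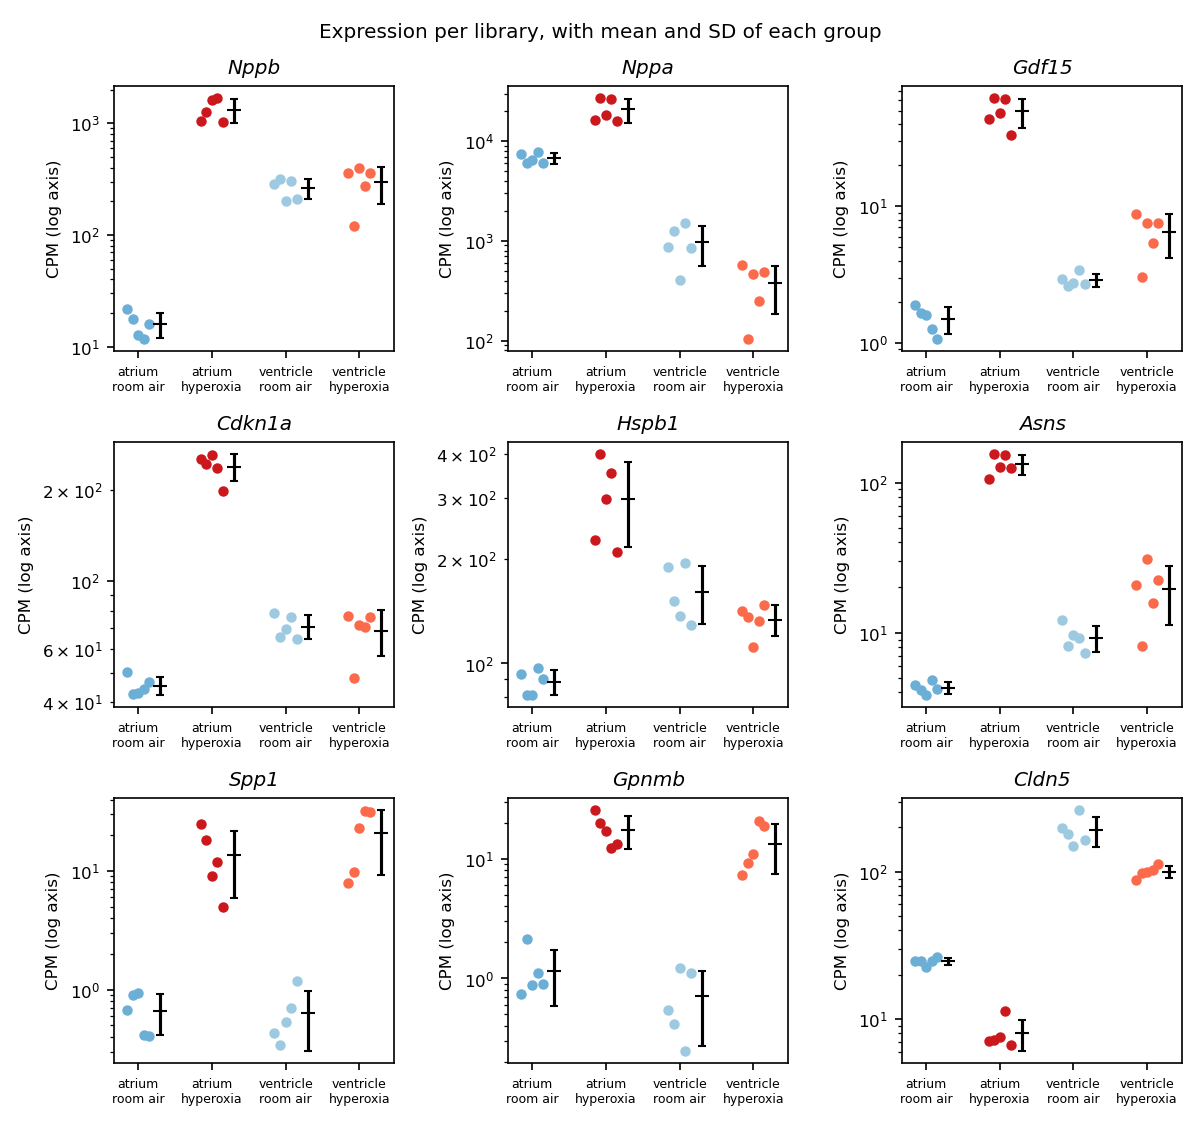
CPM (log axis) of 9 named genes in each of the 20 libraries, as points by group, with the mean and SD of each group as a bar beside them. Nppb averages 1330 CPM in hyperoxic atria and 16 CPM in room-air atria, and 300 and 265 CPM in the ventricles.

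The second comparison put the same question to the left ventricle. Osteopontin (Spp1, chromosome 5) rose from 0.638 ± 0.335 to 20.9 ± 11.7 CPM and the transmembrane glycoprotein Gpnmb from 0.711 ± 0.436 to 13.4 ± 5.97 CPM. Camera called the endothelial list lower and the DNA replication, calcium handling and macrophage lists higher, though most members of the last 3 did not pass. With an estimated correlation it called the endothelial list (adjusted p = 0.022) and not the other 3 (0.45, 0.23 and 0.50). The retinoid-binding protein gene Rbp7 fell from 52.2 ± 14.1 to 20.6 ± 5.51 CPM and the clock gene Per1 from 72.1 ± 24.7 to 28.1 ± 4.13 CPM.

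In the left ventricle 1813 of 16598 genes passed the edgeR test, 936 higher and 877 lower, of which 87 and 137 differed by 2-fold or more. With RLE scaling 834 were higher and 961 lower, and with upper-quartile scaling 801 and 1000. Other large increases were those of the galectin gene Lgals3 (log2 1.37, SE 0.18), the immediate early gene Egr1 (1.34, SE 0.23), the macrophage gene Mpeg1 (1.31, SE 0.17) and Klhl11 (1.3, SE 0.28). The largest decreases also included the bradykinin receptor Bdkrb2 at -1.94 (SE 0.42), the small RNA gene Bc1 at -1.39 (SE 0.32), the matrix protein Ltbp2 at -1.33 (SE 0.28) and the cytokine Mif at -1.32 (SE 0.22). The number of genes passing was 926 without hyperoxic ventricle 5, 978, 1119 and 1083 without room-air ventricle 4, 1 or 2, and 1098 and 1043 without hyperoxic ventricle 4 or 6. It was 257 with Y-linked reads as a covariate, 117 with ventricular Myl7 as a covariate, 309 without 3 ventricular libraries that lay apart (hyperoxic ventricle 4 and room-air ventricles 1 and 4) and 3305 without the 3 tilted libraries. Spp1, Gpnmb, Lgals3, Mpeg1 and Mif passed in all 37 settings tried, with Spp1 at 3.89 with the Myl7 covariate against 5.03 without, and Mif at -0.75 with Y-linked reads and the length slope as covariates. The calls of Egr1, Klhl11, Bdkrb2, Bc1, Per1 and Ltbp2 were lost with the Myl7 covariate, all with a larger SE. There Egr1 was at 1.01 (SE 0.31), Klhl11 at 1.16 (SE 0.39), Bdkrb2 at -1.72 (SE 0.52), Bc1 at -1.47 (SE 0.41), Per1 at -1.39 (SE 0.35) and Ltbp2 at -0.83 (SE 0.30). Without the 3 libraries that lay apart Klhl11 was at 0.92, Bc1 at -0.97, Ltbp2 at -1.17 and Rbp7 at -1.01, and none of them passed. With Y-linked reads and the length slope as covariates Klhl11, Bc1 and Rbp7 passed at 0.56, -0.67 and -0.68, while Egr1 did not pass. With Y-linked reads alone as a covariate Klhl11, Bdkrb2, Bc1 and Ltbp2 did not pass. In the libraries with more Y-linked than Xist reads the calls of Klhl11, Bc1 and Per1 were lost.

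Of 15 endothelial markers measured in the hyperoxic ventricle 8 fell and 7 did not pass (9 fell adjusted over the list alone). These included the adhesion molecule Esam from 171 ± 10.4 to 108 ± 8.17 CPM, Cldn5 from 191 ± 44.0 to 100 ± 9.06 CPM and the lipase anchor of capillaries Gpihbp1 from 182 ± 32.6 to 109 ± 8.03 CPM (camera, adjusted p = 4.8e-09, and adjusted p = 0.022 with an estimated correlation). Among 21 genes of angiogenesis and VEGF signalling 5 fell and 16 did not pass (7 fell and 1 rose adjusted over the list alone), with camera at adjusted p = 0.008 and adjusted p = 0.45 with an estimated correlation. Of 7 measured adipocyte markers 2 fell, 1 rose and 4 did not pass (6 and 1 adjusted over the list alone), including the lipid carrier Fabp4 from 1910 ± 478 to 968 ± 157 CPM, a gene that capillary endothelium also expresses (camera, adjusted p = 0.017, and adjusted p = 0.23 with an estimated correlation). The Fabp4 call was lost with Y-linked reads as a covariate (adjusted p = 0.051) and without the 3 ventricular libraries that lay apart.

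Genes of calcium handling, DNA replication, amino acid stress and macrophages had members that rose. Among 28 genes of calcium handling and ion channels 8 rose and 20 did not pass (10 rose and 4 fell adjusted over the list alone), including the ryanodine receptor Ryr2 from 404 ± 52.1 to 660 ± 76.5 CPM and the calcium pump Atp2a2 from 2380 ± 138 to 3610 ± 476 CPM (camera, adjusted p = 0.0015, and adjusted p = 0.23 with an estimated correlation). Of 44 genes of the G1/S transition and DNA replication 11 rose and 33 did not pass (17 rose adjusted over the list alone), including the helicase subunit Mcm2 at log2 0.48 and the cyclin Ccne2 at 0.77 (camera, adjusted p = 5.6e-06, and adjusted p = 0.45 with an estimated correlation). Of 30 genes of ER stress and the amino acid response 9 rose and 21 did not pass (9 rose and 1 fell adjusted over the list alone), including Chac1 at 2.88, the mitochondrial folate enzyme Aldh1l2 at 1.18 and Gdf15 at 1.17 (camera, adjusted p = 0.049, adjusted p = 0.59 with an estimated correlation and 0.25 in the libraries with more Y-linked than Xist reads). Of 12 macrophage markers 3 rose and 9 did not pass (5 rose adjusted over the list alone), including Adgre1 at 0.76 and the fractalkine receptor Cx3cr1 at 0.66 (camera, adjusted p = 0.019, and adjusted p = 0.50 with an estimated correlation). The calls of Ryr2, Atp2a2, Mcm2, Ccne2, Gdf15 and Adgre1 were lost with ventricular Myl7 as a covariate, where their log2 differences changed little and their SE grew. Those of Ryr2, Ccne2, Adgre1 and Cx3cr1 were lost without the 3 ventricular libraries that lay apart. In the libraries with more Y-linked than Xist reads Cx3cr1 (log2 0.65, adjusted p = 0.063), Mcm2 (0.52, 0.053), Ccne2 (0.62, 0.11) and Gdf15 (0.88, 0.088) did not pass. Ccne2 also did not pass with Y-linked reads as a covariate (0.55, 0.14). Ryr2 went from 0.71 (SE 0.14) to 0.69 (SE 0.19), Atp2a2 from 0.60 (SE 0.12) to 0.51 (SE 0.16) and Mcm2 from 0.48 (SE 0.09) to 0.51 (SE 0.13). Ccne2 went from 0.77 (SE 0.17) to 0.72 (SE 0.24), Gdf15 from 1.17 (SE 0.23) to 1.22 (SE 0.29) and Adgre1 from 0.76 (SE 0.15) to 0.71 (SE 0.21).

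Myl7 averaged lower in the hyperoxic ventricles (38.9 ± 52.9 against 231 ± 203 CPM), and so were several atrial identity genes. Of 20 genes of atrial cardiomyocyte identity 6 were lower, 2 higher and 12 did not pass (11 and 3 adjusted over the list alone), and camera gave adjusted p = 0.049, or 0.59 with an estimated correlation and 0.68 with ventricular Myl7 as a covariate. Nppa was 374 ± 191 CPM in hyperoxia and 981 ± 426 CPM in room air (log2 -1.39, SE 0.35, adjusted p = 0.016). With the Myl7 covariate its call was lost but its difference was not smaller (log2 -1.56, SE 0.41, adjusted p = 0.089). The Nppa call was lost in 9 of 37 settings in all, with log2 from -1.74 to -0.92 over the settings and adjusted p up to 0.13. These included no filter on low counts (0.063), a fit of only the libraries compared (0.085), Y-linked reads as a covariate (0.10) and the length slope as a covariate (0.13). The 2 higher members were the growth factor Bmp10 (189 against 11 counts over the group, log2 4.06) and the potassium channel Kcnj5 (0.67). The Bmp10 difference was 3.36 without hyperoxic ventricle 4 and 5.14 without room-air ventricle 1. With the Myl7 covariate it went from 4.06 (SE 0.76) to 3.56 (SE 1.09) and its call was lost (adjusted p = 0.14). Of 15 genes of ventricular identity 2 rose, the transcription factor Hey2 at 0.98 and the potassium channel Kcnj2 at 0.52, and 13 did not pass (4 rose adjusted over the list alone), with camera at adjusted p = 0.008 and adjusted p = 0.39 with an estimated correlation. The Kcnj2 call was lost with either covariate, with Myl7 at 0.42 (SE 0.13) against 0.52 (SE 0.10).

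Ribosomal protein genes had a median log2 difference of -0.52 in the ventricle. There 2 of 38 fell and 36 did not pass (27 fell adjusted over the list alone). Camera gave adjusted p = 2.2e-09, 0.59 with an estimated correlation and 0.17 with the length slope as a covariate, and room-air ventricle 4 was the tilted library of this comparison. Rpl38 was at -0.87, and without room-air ventricle 4 it had adjusted p = 0.14. Its call was also lost without any of the 5 hyperoxic ventricles, room-air ventricle 1 or 2, or room-air atrium 2. Of 53 nuclear genes of oxidative phosphorylation 1 rose, 1 fell and 51 did not pass (0 and 0 adjusted over the list alone), with a median of -0.38 (camera, adjusted p = 8e-05 downward, adjusted p = 0.74 with an estimated correlation, and adjusted p = 0.0092 upward with the length slope as a covariate).

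Of the genes named in advance, Fasn was at log2 0.45 (adjusted p = 0.038), a call lost in 13 of 37 settings (log2 down to 0.20, adjusted p up to 0.22). These were 7 that left out 1 library, no filter on low counts, the Y-linked reads, the length slope, both together or Myl7 as covariates, and leaving out the 3 libraries that lay apart. The other 6 besides Nppa did not pass. Vegfa was at 0.17 (adjusted p = 0.44), Mki67 at 0.20 (0.25), Scd1 at 0.13 (0.53), Cdkn1a at -0.05 (0.80), Nqo1 at -0.05 (0.82) and Myl2 at -0.37 (0.80). Of 34 p53 targets 6 rose and 1 fell (6 and 3 adjusted over the list alone), with camera at adjusted p = 0.096. Of 28 NRF2 antioxidant genes 0 rose and 1 fell (0 and 0 adjusted over the list alone), with camera at adjusted p = 0.34.

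**Figure D3:**
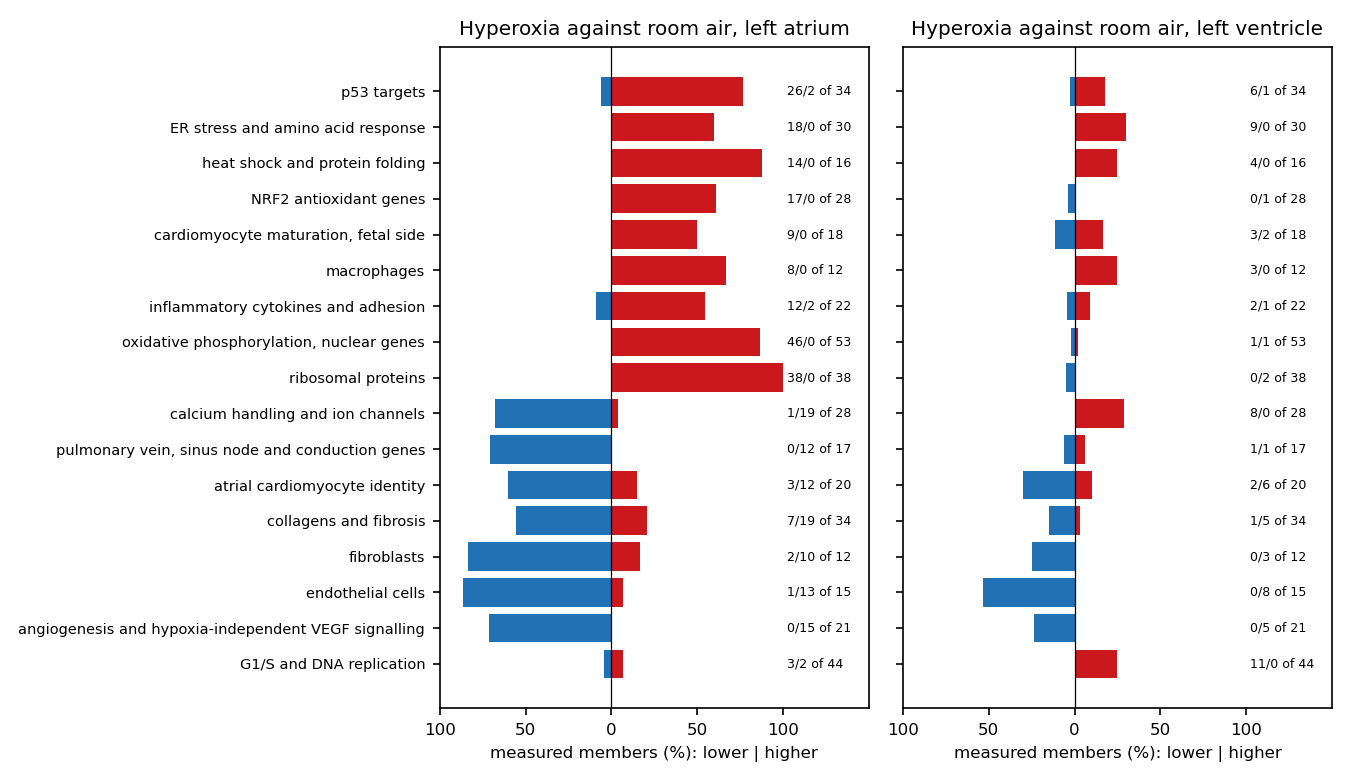
Percent of the measured members of 17 fixed gene lists that were higher (red, right) or lower (blue, left) in hyperoxia by the edgeR test, in the left atrium and the left ventricle, with the counts beside each bar. In the atrium 26 of 34 p53 targets were higher and 13 of 15 endothelial markers lower, and in the ventricle 6 of 34 and 8 of 15.

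The series title names distinct responses of the chambers, so the difference between the 2 responses was tested itself. Nmrk2, Nppb, Asns and Cldn23 rose more in the atrium than in the ventricle, by log2 differences of 7.13 (SE 0.88), 6.20 (SE 0.37), 3.87 (SE 0.32) and 4.81 (SE 0.97). Nmrk2 was 152 ± 94.3 CPM in hyperoxic and 167 ± 114 CPM in room-air ventricles, and Nppb 300 ± 110 and 265 ± 54.3 CPM. The response of Ky was lower in the atrium by -3.28 (SE 0.33), that of the splicing regulator Rbfox1 by -3.02 (SE 0.25) and that of Clca3a2 by -2.98 (SE 0.59). The edgeR test called 6060 genes, 2824 with a more positive response in the atrium and 3236 with a more negative one. With RLE scaling these were 3099 and 2894, and with upper-quartile scaling 3250 and 2724.

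Camera called the p53, calcium channel, NRF2, heat shock and amino acid lists as differing in response between the chambers. With an estimated correlation only the p53 and calcium channel lists of these were called (adjusted p = 0.021 each, against 0.16, 0.27 and 0.098). Of 34 p53 targets 23 had a more positive atrial response and 2 a more negative one (24 and 2 adjusted over the list alone), including Cdkn1a at 2.44, Gdf15 at 3.86 and the cell death effector Bax at 2.06 (camera, adjusted p = 2e-11, and adjusted p = 0.021 with an estimated correlation). Of 28 genes of calcium handling and ion channels 18 had a more negative atrial response (19 adjusted over the list alone), including Kcnj2 at -1.72, Kcnh2 at -1.61 and Atp2a2 at -1.36 (camera, adjusted p = 3.2e-07, and adjusted p = 0.021 with an estimated correlation). Atp2a2 fell in the hyperoxic atria from 4400 ± 610 to 2610 ± 276 CPM and rose in the ventricles. The amino acid and ER stress list had 17 more positive and 1 more negative response of 30, with the same counts adjusted over the list alone and Trib3 at 3.73. Among 28 NRF2 genes 14 were more positive (17 adjusted over the list alone), including the epoxide hydrolase Ephx1 at 1.23, and among 16 heat shock genes 12, with Hspb1 at 2.01 and the same count adjusted over the list alone. Of 18 fetal-side genes 9 were more positive, over all genes and adjusted over the list alone, including the skeletal actin gene Acta1 at 2.7. Camera gave adjusted p = 7.3e-10, 1.4e-06, 3.6e-07 and 0.0018 for these 4 lists, and with an estimated correlation adjusted p = 0.098, 0.16, 0.27 and 0.098.

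All 38 ribosomal protein genes and 45 of 53 nuclear genes of oxidative phosphorylation also had a more positive atrial response (38 and 47 adjusted over the list alone), along with the tilted libraries of both chambers. By camera their adjusted p = 1.9e-17 and 7.7e-14, and with an estimated correlation 0.43 and 0.50. With the length slope as a covariate the second list had adjusted p = 0.59. Without hyperoxic ventricle 5 the share of more positive responses among the genes passing was 57.0%, against 46.6% with all libraries. The difference of the median gene moved there by log2 0.073, a shift of scale. With the length slope as a covariate 2628 genes passed. Among the genes with the largest differences, Uts2b (a urotensin) had 2 counts in the hyperoxic ventricles, Irx4 3 counts and the calcium channel subunit Cacng6 2 counts in the hyperoxic atria. Their fitted differences of 5.35, -4.08 and -3.39 depend on the prior count. The Irx4 value was 0.68 without room-air atrium 1, and its call was also lost without any of the 5 hyperoxic atria, hyperoxic ventricle 5 or room-air ventricle 4, and with the replicate block. It held in 17 of 35 settings. The Uts2b and Cacng6 calls were lost with voom quality weights and with the replicate block as a random effect (adjusted p over all settings up to 0.21 and 0.067). That of Uts2b was also lost with the length slope or Myl7 as a covariate. Uts2b had 7.56 without hyperoxic ventricle 1 and 4.69 without room-air ventricle 5. Cldn23 had 5.86 without hyperoxic ventricle 4, and Clca3a2 -3.61 without room-air ventricle 5.

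The overlap of the 2 responses was also counted. Of the genes passing in both chambers (911), 340 were higher in both and 296 lower in both, against 184.5 and 212.4 expected from the separate counts. Another 121 were higher in the atrium and lower in the ventricle against 172.8, and 154 the reverse against 226.7. Across genes, which are not independent replicates, Pearson's r between the log2 differences was 0.113 and Spearman's rho -0.024. Of 100 permutations of the oxygen labels 38 gave an r as large in size, and 5 gave a covariance as large in size as the observed 0.0442. The labels of atria and ventricles were permuted separately, so possible pairs by number were not kept. In 0 permutations did any gene pass in both chambers, but the number expected from the separate counts was also 0 in each. The permutations therefore do not test the number of shared genes.

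The chambers themselves were compared in room air. Irx4, a ventricular transcription factor gene (63.2 ± 3.88 against 0.294 ± 0.644 CPM), and Myl2 (20400 ± 5310 against 73.5 ± 142 CPM) marked the ventricle. Myl7 (7010 ± 837 against 231 ± 203 CPM), Nppa (6790 ± 816 against 981 ± 426 CPM), the potassium channel Kcnh7, Sbk3, Uts2b and Clca3a2 marked the atrium, the last 4 by log2 7.86, 6.79, 6.58 and 6.51. Cacng6 and the tubulin Tuba8 were lower in the atrium by log2 -6.45 and -6.42. In all, 9122 genes passed, 4762 higher and 4360 lower in the atrium. The larger side turned with upper-quartile scaling (4434 and 4684), with a filter of 1 CPM in 5 libraries (3693 and 4919) and without hyperoxic ventricle 5 (3956 and 5187). In these settings the median gene moved by log2 -0.039, -0.097 and -0.093, so the turn went with a shift of scale. Without room-air atrium 1, which held ventricular transcripts, Irx4 was at -12.57 against -7.81 with all libraries and Myl2 at -11.00 against -8.12. Without room-air ventricle 5, Uts2b was at 7.25 and Clca3a2 at 7.14.

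In room air camera called connective tissue, endocardial and macrophage lists higher in the atria, and metabolic, sarcomere and endothelial lists higher in the ventricles. With an estimated correlation it called none of these (adjusted p = 0.074 to 0.28). Of 20 genes of atrial identity 18 were higher in the atrium and 1 lower (19 and 1 adjusted over the list alone), including Gja5 at log2 3.6 and Tbx5 at 3.47. Of 15 genes of ventricular identity 11 were lower and 2 higher (12 and 2). Among 34 collagens and fibrosis genes 28 were higher and 2 lower, including elastin, Eln, at 22500 ± 3220 against 989 ± 164 CPM and tenascin C, Tnc, at 586 ± 83.0 against 59.6 ± 5.99 CPM. Of 12 fibroblast markers 11 were higher and 1 lower (Fbln1 at 2.71), of 7 endocardial markers 6 and 1 (the natriuretic peptide clearance receptor Npr3 at 3.17), and of 12 macrophage markers 11 and 0 (Csf1r at 1.43), with the same counts for these 4 lists adjusted over the list alone. Of 15 endothelial markers 10 were lower and 2 higher, also adjusted over the list alone, with Gpihbp1 at -3.08 and Cldn5 at -2.95. Camera gave adjusted p = 5.5e-11, 2.6e-06, 7.3e-12, 3.4e-05, 0.00066, 0.0012 and 1.9e-05 for these 7 lists in turn, and with an estimated correlation adjusted p = 0.074, 0.074, 0.20, 0.13, 0.20, 0.22 and 0.074.

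All 53 nuclear genes of oxidative phosphorylation were lower in the room-air atrium, including cytochrome c1 (Cyc1) at -1.39, as were 21 of 22 genes of the tricarboxylic acid cycle (Sdha at -0.92) and 30 of 33 genes of fatty acid uptake and oxidation. Adjusted over the list alone these counts were 53, 22 and 30, with 1 fatty acid gene higher. The fatty acid transporter Cd36 was 262 ± 19.8 CPM in atria and 985 ± 38.2 CPM in ventricles, and the uncoupling protein Ucp3 3.69 ± 0.519 and 46.3 ± 3.65 CPM. Of 25 sarcomere genes 19 were lower and 3 higher, also adjusted over the list alone, including Myh7 at -5.19 and Myl3 at -3.87. Cell cycle genes were lower too, 26 of 44 of the G1/S list with 1 higher and 34 of 52 of the mitosis list with 0 higher (26 and 1, and 36 and 0, adjusted over the list alone), including the cyclin Ccnd1 at -2.74 and the centromere protein Cenpa at -1.15. Camera gave adjusted p = 4.8e-19, 6.5e-10, 1.3e-18, 1.5e-05, 1.9e-05 and 2.4e-07 for these 6 lists, and with an estimated correlation adjusted p = 0.28, 0.20, 0.074, 0.20, 0.35 and 0.31. Of 7 adipocyte markers 6 were lower and 0 higher, also adjusted over the list alone, including Cidea at -3.66 and Fabp4 at -3.36 (camera, adjusted p = 4.3e-05, and adjusted p = 0.018 with an estimated correlation). All 4 mast cell markers were lower, also adjusted over the list alone, including the tryptase Tpsb2 at -3.59 (camera, adjusted p = 0.0011, and adjusted p = 0.20 with an estimated correlation). Camera called 28 of 53 lists, a number that 5 of 100 splits reached, the real split included.

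After hyperoxia 8098 genes differed between atrium and ventricle, 4181 higher and 3917 lower in the atrium. The larger side turned in 6 settings, among them a filter of 1 CPM in 5 libraries (3765 and 3848), the length slope as a covariate (4376 and 4552) and leaving out hyperoxic ventricle 5 (3722 and 3841). With RLE scaling the counts were 4438 and 3695. Nppa was 20900 ± 5640 CPM in atria and 374 ± 191 CPM in ventricles (log2 5.80, SE 0.42), and Myl7 7350 ± 3200 and 38.9 ± 52.9 CPM. Uts2b had 12520 counts in atria and 2 in ventricles, a ratio of 4850 with a 95% exact counting interval of 1340 to 40000. Kcnh7, the growth factor family gene Fgf12 and the myosin-binding protein Mybphl were higher in the atrium by log2 8.44, 8.16 and 8.05. Irx4 had 3 counts in atria and 10869 in ventricles, a ratio of 4680 with an interval of 1600 to 22700, and Cacng6 2 and 1894, a ratio of 1220 with an interval of 338 to 10100. Myl2 and the membrane protein Lrtm1 were lower in the atrium by log2 -10.47 and -7.78. Without hyperoxic ventricle 1, which had the most Myl7 of its group, Uts2b, Kcnh7, Fgf12, Mybphl and Myl7 were at 14.15, 10.63, 9.55, 9.39 and 8.78, against fitted values of 11.93, 8.44, 8.16, 8.05 and 7.56 with all libraries. Irx4 was at -12.78 without hyperoxic atrium 3, against -11.89.

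Of 30 genes of ER stress and the amino acid response 28 were higher in hyperoxic atria than in hyperoxic ventricles and 0 lower, also adjusted over the list alone, including the serine synthesis enzyme Phgdh at 2.66 and the amino acid transporter Slc7a5 at 1.93 (camera, adjusted p = 3.2e-14, and adjusted p = 0.025 with an estimated correlation). All 12 macrophage markers were higher, also adjusted over the list alone, including Cd68 at 1.67 and the complement gene C1qc at 1.26 (camera, adjusted p = 1.2e-06, and adjusted p = 0.068 with an estimated correlation). Of 52 mitosis genes 50 were lower and 0 higher (51 and 0 adjusted over the list alone), including Mki67 at -1.14 and the cyclin Ccna2 at -0.82 (camera, adjusted p = 3.2e-14, and adjusted p = 0.12 with an estimated correlation). Of 28 genes of calcium handling and ion channels 20 were lower and 3 higher (20 and 4 adjusted over the list alone), including phospholamban, Pln, at -4.06 (camera, adjusted p = 1.2e-06, and adjusted p = 0.025 with an estimated correlation). Of 21 genes of angiogenesis and VEGF signalling 16 were lower and 1 higher, also adjusted over the list alone, including the apelin receptor Aplnr at -4.96 and the VEGF receptor Kdr at -2.72 (camera, adjusted p = 3.1e-07, and adjusted p = 0.068 with an estimated correlation). Atrial identity genes were higher in 17 and lower in 2 of 20 (18 and 2 adjusted over the list alone), with Dkk3 at 4.18 and the potassium channel Kcna5 at -3.11. Ventricular identity genes were lower in 13 and higher in 1 of 15, also adjusted over the list alone, with Hey2 at -3.49. For them camera had adjusted p = 1.3e-09 and 3.6e-10, and with an estimated correlation adjusted p = 0.068 and 0.025.

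Ribosomal protein genes, lower in the room-air atrium than in the ventricle in 35 of 38 (37 adjusted over the list alone), were higher in the hyperoxic atrium in 34 of 38 (37 adjusted over the list alone), including Rps19 at 0.95 and Rpl4 at 0.60. The camera adjusted p = 1.2e-06 and 5.5e-05, with an estimated correlation 0.49 and 0.56, and the second was 0.081 without the 3 tilted libraries. Of 53 nuclear genes of oxidative phosphorylation 14 were lower in the hyperoxic atrium and 0 higher (13 and 0 adjusted over the list alone), including Sdha at -0.76 (camera, adjusted p = 0.00034, and adjusted p = 0.64 with an estimated correlation).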

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

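The tests that leave out the tilted libraries or use the length slope, the comparison with matched genes per library, and the counts of library splits for genes, were chosen after the results were seen.

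Ribosomal protein and nuclear oxidative phosphorylation genes were higher in the hyperoxic atria, of which 2 tilted towards short transcripts. Both lists rose more than genes matched on annotated exon length and expression level. The 10000 matched sets had medians of 0.32 and 0.35, against 0.79 and 0.66 for the lists, which exceeded 100% and 99.88% of the sets. Since members of a list vary together (correlation 0.93 and 0.86), the excess over matched genes was also compared per library. It was 0.53 ± 0.22 against 0.14 ± 0.06 and 0.16 ± 0.20 against -0.16 ± 0.04 log2 in hyperoxic and room-air atria (n = 5 each, two-sided exact permutation p = 0.0079 for both). Exon length here covers all annotated exons of a gene (median 1800 and 1918 bases) and can exceed the length of the transcript made. The matching therefore does not decide whether transcript length and expression level alone are the source. Without the 3 tilted libraries the ribosomal median went from 0.79 to 0.35, a value between the bounds set for that test, so that most of the size went with those libraries while 30 of 38 genes still passed. With the length slope as a covariate the ribosomal median was 0.23 (27 of 38 passing), or 0.22 with Y-linked reads added. No bound was set for these covariates. The oxidative phosphorylation median went from 0.65 to 0.21 (20 of 53 genes passing), or to 0.11 and 0.02 with those covariates, which is consistent with the tilt as the main source of this list's rise. For the ribosomal list the tilt and a response to hyperoxia cannot be told apart, because 2 of 5 hyperoxic atria are tilted and camera had adjusted p = 0.55 with an estimated correlation.

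Both room-air groups held 5 libraries with more Y-linked than Xist reads, the hyperoxic atria 1 and the hyperoxic ventricles 2. With Y-linked reads as a covariate the median signed log2 difference of the called genes was 1.07 times its value in the atrium and 0.85 times in the ventricle (leave-one-out 0.92 to 1.14 and 0.77 to 0.95). This argues against sex as the whole source, provided that sex acts alike in both chambers. The model held 1 slope on Y-linked reads for both chambers, set mainly by the hyperoxic libraries. Among hyperoxic atria only number 2 had more Y-linked than Xist reads, and it was also tilted towards short transcripts. In the ventricle 257 genes passed with the covariate, against 1813: the median went from 0.50 (median SE 0.12) to 0.43 (0.15), so calls ended through the larger error as well as the smaller size. All 1813 kept their direction. Sex, which is not in the labels, stays open as a contribution to single genes, since only 1 hyperoxic atrium had more Y-linked than Xist reads.

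Some atrial genes were lower in the hyperoxic ventricles (6 of 20 atrial identity genes, with 2 higher), where Myl7 averaged 38.9 CPM against 231 CPM in room air. The 42 genes at least 16-fold higher in room-air atria had a median log2 difference of -0.71, and 0 with ventricular Myl7 as a covariate (10 called lower without it, 0 with it). Carried-over atrial tissue would give this, but so would lower expression of Myl7 and other atrial genes in ventricular cells. The covariate cannot tell these apart. Ventricular Myl7 CPM averaged 3.3% of the atrial mean in room air and 0.529% in hyperoxia. These are shares of carried-over tissue only if all ventricular Myl7 was carried over. A mixture with these shares predicted the larger part of the log2 difference for 1.3% of the 1813 called genes (23), which argues against it as the source of the ventricular calls at large. With the Myl7 covariate 117 genes passed and the median signed difference went from 0.50 (SE 0.12) to 0.47 (0.16). For Nppa, carry-over and lower expression cannot be told apart: with the Myl7 covariate its log2 difference went from -1.39 (SE 0.35) to -1.56 (SE 0.41), and after subtraction the ratio of hyperoxic to room-air means was 0.35 (264 ± 202 against 757 ± 572 CPM, two-sided exact permutation p = 0.12), a difference in means that 5 libraries per group did not separate.

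In 17 of 296 groups tested 1 library lay far from the other 4 by Dixon's ratio (critical value 0.71). Chance flags about 1 in 20 groups. Hyperoxic atrium 1 had 0.629% haemoglobin counts, against 0.186 to 0.3% in the others. The gene values in CPM were Scd1 in hyperoxic atrium 2 (7.51, others 9.6 to 10.3), Nqo1 in hyperoxic atrium 2 (10.6, others 9.16 to 9.52), Myl2 in room-air atrium 1 (328, others 7.42 to 15), Kcnh2 in hyperoxic atrium 4 (63.2, others 82.6 to 88.5), Etv1 in hyperoxic atrium 5 (17.7, others 12.6 to 12.9). They also were Etv1 in room-air atrium 5 (36.7, others 26.7 to 27.9), Cldn5 in hyperoxic atrium 4 (11.4, others 6.62 to 7.58), Ccl2 in hyperoxic atrium 2 (27.2, others 9.58 to 14.5), Bc1 in room-air ventricle 4 (17.7, others 6.49 to 9.64), Cdkn1a in hyperoxic ventricle 2 (48, others 70.4 to 76.9), Kcnh7 in room-air atrium 5 (30.2, others 21.3 to 23.5). The rest were Gja5 in room-air ventricle 4 (26.7, others 18.3 to 19.4), Myh7 in room-air atrium 1 (18.5, others 6.67 to 8.64), Mybphl in hyperoxic ventricle 1 (5.5, others 0.247 to 1.74), Kdr in hyperoxic ventricle 1 (233, others 257 to 266), Cd68 in hyperoxic ventricle 4 (5.34, others 7.41 to 8.23).

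The edgeR test of the difference called 61 of the 80 genes named in the hyperoxia comparisons or for the difference itself, which were picked by rule and are no random sample. The atrial log2 response to hyperoxia was more positive than the ventricular one for Nmrk2 (7.13), Nppb (6.2), Uts2b (5.35), Cldn23 (4.81), Asns (3.87), Gdf15 (3.86), Trib3 (3.73), Hspa1a (3.36), Bc1 (3.14), Nppa (3.01), Osgin1 (2.76) and Acta1 (2.7). Smaller positive differences were those of Cdkn1a (2.44), Chac1 (2.34), Bdkrb2 (2.18), Mif (2.08), Rpl38 (2.07), Bax (2.06), Hspb1 (2.01), Sesn2 (1.86), Lgals3 (1.7), Cox6a2 (1.65), Ankrd1 (1.62) and Rps19 (1.61). The positive side also held Acot2 (1.47), Aen (1.38), Cd68 (1.26), Srxn1 (1.26), Ephx1 (1.23), Icam1 (1.12), Emcn (0.93), Igf2bp2 (0.85) and Esam (0.3). On the negative side the differences were those of Irx4 (-4.08), Cacng6 (-3.39), Ky (-3.28), Rbfox1 (-3.02), Clca3a2 (-2.98), Pi15 (-2.64), Col22a1 (-2.46), Hey2 (-2.18) and Gja5 (-1.98). Less negative were Cldn11 (-1.77), Kcnj2 (-1.72), Kcnh2 (-1.61), Ryr2 (-1.59), Kcnj5 (-1.43), Col6a3 (-1.42), Klhl11 (-1.4), Atp2a2 (-1.36) and Etv1 (-1.13). The least negative were Lum (-1.09), Tbx5 (-1.09), Per1 (-1.03), Fasn (-0.94), Ccne2 (-0.75), Cldn5 (-0.7), Pi16 (-0.69), Aldh1l2 (-0.61), Mki67 (-0.56) and Mcm2 (-0.43).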

How the results depend on the processing

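Settings that leave out tilted or outlying libraries, keep libraries with more Y-linked than Xist reads, or use the length slope or Myl7 as covariates were chosen after the results were seen. Of 45 named genes that passed in the atrium 5 lost the call in at least 1 setting, of 32 in the ventricle 20 and of 20 for the difference 3, while all 30 and 25 of the chamber comparisons in room air and hyperoxia kept it. The genes passing without single libraries numbered 6381 to 7761 in the atrium, 926 to 2527 in the ventricle, 5146 to 6645 for the difference, and 8347 to 9538 and 7563 to 8393 between the chambers. The highest ventricular count came without hyperoxic atrium 2, a tilted library, and the highest atrial count without hyperoxic ventricle 4. Neither library is in the comparison concerned, but all groups share 1 estimate of the spread. With replicate numbers as a replicate block the genes passing numbered 7759, 2596, 6185, 8965 and 7420. For the first 2 counts the block joined hyperoxic and room-air libraries of equal number, which are different pups, so it was no block by animal. For the other 3 it joined atrium and ventricle of equal number within an oxygen level. Number 6 occurred only in hyperoxic ventricle 6, which such a block fits exactly. The block within an oxygen level also fits hyperoxic atrium 3 exactly, since there is no hyperoxic ventricle 3. That block therefore rests on 4 hyperoxic pairs. Correlation by number was weak, with r of 0.023 to 0.319 in 9 same-number pairs (mean 0.116, other pairs -0.025) and a consensus correlation of 0.135. Of the 9 atria 4 correlated best with the ventricle of their own number. In 4 of 4 hyperoxic same-number pairs atrium and ventricle agreed on whether Y-linked or Xist reads were more. Whether equal numbers are 1 pup stays open. The fit on only the libraries compared gave no value for the difference, which uses all 20. Depth limits genes with few counts, such as Irx4, Uts2b and Cacng6, whose fitted values rest on 2 or 3 counts in a group.

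The ventricular count of 1813 was 1021 with no filter, where more genes were tested, 2768 with DESeq2, 2965 with voom quality weights and 257 with Y-linked reads as a covariate. It was 3305 without the 3 tilted libraries, 277 with the libraries of more Y-linked than Xist reads and 309 without 3 outlying ventricles, the last 2 with fewer libraries. Ventricular Myl7 as a covariate gave 117, and Y-linked reads with the length slope 1050. With the last setting the atrial count was 4538 and that of the difference 2623, and with the length slope alone the latter was 2628. At an adjusted p under 0.10 the genes passing in both chambers were 1840. An estimated correlation left 5, 1, 2, 1 and 7 lists in the 5 comparisons, and fry called 33 in the atrium and 43 between the chambers in room air. Where no construction is named, the cause was not tested.

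In the atrium Scd1 changed sign, to 0.02 with RLE scaling, 0.03 with upper quartiles, 0.07 with the 1 CPM filter, 0.02 with DESeq2, 0.09 with voom, 0.05 on the libraries compared, 0.06 without tilted libraries, 0.10 with the slope and 0.08 with slope and Y-linked reads (leave-one-out -0.05 to 0.06). Nqo1 was -0.11 with the slope and -0.17 with slope and Y-linked reads (leave-one-out 0 to 0.13). The leave-one-out range of Myl2 was -3.13 to 0.17, and that of Irx4 in the difference -4.97 to 0.68, each upper value without room-air atrium 1. In the ventricle Cdkn1a was 0.03 with voom and 0.03 without outlying libraries (leave-one-out -0.09 to 0.06). Nqo1 was 0.04 with voom, 0.10 without tilted libraries, 0.10 with the slope, 0.04 without outlying libraries and 0.07 with slope and Y-linked reads (leave-one-out -0.11 to 0.10). Mki67 was -0.03 with slope and Y-linked reads, and Vegfa -0.03 with the slope. For these genes the cause was not tested, apart from Myl2, where 1 library held the reads.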

Other observations

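The counts of library splits for genes, and those per list, were chosen after the results were seen.

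Several lists not described so far were also called. In the hyperoxic atrium 15 of 22 tricarboxylic acid cycle genes rose and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 0.00015), as did 16 and 2 of 36 interferon response genes (17 and 2, adjusted p = 0.0042) and 12 and 3 of 19 other antioxidant genes (the same counts, adjusted p = 0.021). With an estimated correlation their adjusted p = 0.55, 0.66 and 0.63. In the hyperoxic ventricle 3 of 12 fibroblast markers fell (7 adjusted over the list alone, camera adjusted p = 0.0089), as did 2 of 9 replication-dependent histones (4, with 1 higher, adjusted p = 0.0089) and 2 of 10 T cell markers (4, adjusted p = 0.0018). With an estimated correlation these were 0.42, 0.39 and 0.42.

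In room air all 8 mitochondrially encoded mRNAs were lower in the atrium than in the ventricle (8 adjusted over the list alone, camera adjusted p = 0.00011, and 0.20 with an estimated correlation). So were 6 of 7 B cell markers (6, adjusted p = 0.0018 and 0.13) and 21 of 36 interferon response genes, with 2 higher (21 and 2, adjusted p = 0.00037 and 0.37).

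Other splits of the same libraries were also fitted. The real split was the 1 of 100 with as many genes in each comparison, which is the lowest number possible. It is not corrected over the 5 comparisons. The other splits mix the groups, so that a difference between the groups widens the spread within each split. Chance is therefore not excluded by this test for the 5 counts of genes. These were 7291 against a highest other of 3621 in the atrium, 1813 against 35 in the ventricle, 6060 against 4495 for the difference, 9122 against 0 between the chambers in room air and 8098 against 1675 in hyperoxia. The highest other atrial split exchanged 1 library per group, and that of the difference kept the atrial labels and exchanged most ventricular ones.

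For the number of lists called by camera, 4 of 100 splits reached as many in the ventricle (20 against a highest other of 20). Between the chambers in hyperoxia 3 of 100 did (31 against 31). These shares include the real split and are not corrected over the 5 comparisons, so chance is not excluded for either. Nor can chance be excluded in the atrium (31 of 100, 20 against 26), for the difference (29 of 100, 17 against 29) or between the chambers in room air (5 of 100, 28 against 30). The median of the other splits was 17 lists in the atrium and 10 in the ventricle, and these splits carry part of the oxygen effect, since they mix the groups in unequal shares.

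Each list was also compared with the splits, by how many of 100 gave as small a camera p. The numbers include the real split, so 1 is the lowest possible, and they are not corrected over the 53 lists of a comparison. Even a number of 1 therefore does not exclude chance for a single list. Where chance is called not excluded below, this holds even without correction. In the atrium the number was 1 for the p53, heat shock and amino acid lists, 2 for the fetal-side list, 3 for the endothelial and fibroblast lists and 4 for the conduction list. It was 6 for angiogenesis, 7 for NRF2 genes, 9 for calcium handling and 10 for inflammatory genes. Chance cannot be excluded for those 4, nor for macrophages (20), atrial identity (21), the tricarboxylic acid cycle (24), ribosomal proteins (35), interferon response (36), collagens (39), oxidative phosphorylation (40), other antioxidant genes (40) and fatty acid oxidation (41). In the ventricle it was 1 for endothelial markers, 2 for angiogenesis, 3 for adipocyte markers and 4 for calcium handling and ventricular identity. Chance cannot be excluded there for histones (10), macrophages (13), G1/S genes (15), T cells (16), fibroblasts (17), ribosomal proteins (18), the amino acid list (29), atrial identity (37) and oxidative phosphorylation (43). For the difference it was 1 for NRF2 genes, 2 for the p53, amino acid and calcium lists, 4 for the heat shock and fetal-side lists, 5 for ribosomal proteins and 18 for oxidative phosphorylation, and chance cannot be excluded for the last 2. Nor can it be excluded for the other lists camera called there. These were other antioxidant genes (8), conduction (8), antigen presentation (17), fibroblasts (20), interferon response (24), inflammatory genes (26), angiogenesis (32), mitosis (37) and the tricarboxylic acid cycle (44).

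Between the chambers in room air it was 1 for atrial and ventricular identity, collagens, fibroblast, endocardial, endothelial and adipocyte markers and fatty acid oxidation, and 4 for the tricarboxylic acid cycle. Chance cannot be excluded there for oxidative phosphorylation (6), B cells (12), sarcomere genes (14), mast cells (17), macrophages (18), mitochondrially encoded mRNAs (24), G1/S genes (34), interferon response (38), mitosis (39) and ribosomal proteins (45). In hyperoxia it was 1 for the amino acid, calcium, angiogenesis and both identity lists and 4 for macrophages and mitosis, and chance cannot be excluded for ribosomal proteins (43) and oxidative phosphorylation (70).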
